A study of Rattus norvegicus with 3 samples.

How the data were processed

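Gene expression was measured in donor kidneys of male Wistar rats (370 to 508 g) in a model of donation after cardiac death. Per the labels' protocols, kidneys were left for 20 min of warm ischaemia, stored cold for 17 ± 0.7 h in University of Wisconsin solution and then perfused by the femoral artery of a recipient rat for 5 h 43 min ± 21 min (the kind of error is not given in the sources used here). Recipients received saline at 1 ml/h (control), heparin at 100 U/ml/h, or a peptide called peptide 2 at 0.5 mg/ml, with 7 recipients per group. The series' design text speaks of a bolus and the treatment protocol of an infusion. Total RNA of 3 of the 7 kidneys of each group, those with the best RNA quality, was pooled in equimolar amounts. Biotin-labelled cRNA was made from 6 µg and hybridised to an Affymetrix rat expression array, which measures each transcript with a set of short probes (a probe set).

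The deposited values are log2 expression values per probe set, 1 column per array. GCRMA, which corrects the background by probe sequence and summarises the probes of a set, is named without a version in the submitters' processing notes. Its settings, and any normalization between arrays, are not given in the sources used here. The values were used as deposited. All 3 arrays had the same lowest value, 2.18. On the control, heparin and peptide arrays 30.9%, 29.5% and 30.9% of probe sets lay within 0.01 of it. The medians were 4.14, 4.16 and 4.14. Many genes had exactly the same value on different arrays: of 9231 genes measured on all 3 arrays, 54.3% had at least 2 identical values and 22.4% had 3. A difference of exactly 0 can therefore come from the summarisation and does not show that a transcript was equally abundant. Arrays have no read depth, and the number of arrays, 1 per group, limits the precision.

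Of 31099 probe sets, 20832 had 1 gene symbol in the platform annotation, 436 had several and 9831 had none (57 probe sets were array controls). Of the probe sets with 1 symbol, 20764 had a gene ID found in a RefSeq gene table of the GRCr8 assembly, and 0 of these carried a different symbol there. They stood for 14218 genes, 4526 of them with more than 1 probe set. A gene was represented by the probe set with the highest mean over the 3 arrays. Probe sets with no symbol or several were not named.

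A gene counted as measured in a comparison when its value was at or above the median of all probe sets on both arrays. This left 9236 genes for heparin against control, 9268 for peptide against control and 9240 for heparin against peptide. Differences of log2 values were taken between arrays, and genes with a difference of at least 1 (2-fold) were counted. With 1 array per group there is no replicate check of any difference, so no test was made, and no p-value, standard error or replicate SD is given. Genes below the median on one array and at or above its 60th percentile on the other have only a bound: the bright value minus the higher of the dim value and the dim array's median.

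Before the data were examined, 40 gene lists (pathways, cell types and tubule segments, 985 different names), the comparisons, the thresholds and a rule for the genes to be named were fixed. The rule took the 10 genes with the largest positive and the 10 with the largest negative difference against control for each treatment, and the 5 and 5 between treatments. Genes were left out if another measured probe set of the gene went the other way, or if their name was only a locus number. It also took up to 3 bounds per direction for each comparison with control, up to 4 measured members of each list with the largest absolute difference, and Ccl5, Ccr1, Ccr3, Ccl2, Icam1, Vcam1, Havcr1, Lcn2 and Hmox1. Some other genes fixed in advance were not analysed here. Genes named outside this rule are marked as chosen after their values were seen. Of 1048 list entries, 883 matched by symbol and 18 by a synonym, and 147 were not matched, which left 836 different genes. For each list with at least 5 measured members, the median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A median below the 2.5th or above the 97.5th percentile is called outside the random lists, which describes these arrays and is not a test of the treatment. Because so many differences are exactly 0, medians of random lists crowd near 0, and a list median can lie outside them while being small.

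Both treatments were compared with the same control array. Chance values shared in this way were simulated 1000 times with arrays that do not differ. The count of genes was tested on simulated data for heparin against control, with 9237 genes measured and noise with an SD of 0.165 per array. Of genes changed 4-fold, 2-fold and 1.5-fold, 100%, 50.7% and 1.5% were counted at 2-fold, with 0 unchanged genes. The noise was set from the peptide and control arrays, whose gene differences had an SD of 0.23, against 0.32 for heparin and control. The 0 therefore follows from that setting and does not show how many unchanged genes pass on the real arrays. The lists were tested on the same simulated arrays for peptide against control, with fewer random lists. A list shifted by 0.5 lay at the 100th percentile, and 2 of 36 unshifted lists lay outside the random lists. Noise was drawn separately for each probe set, so this does not cover lists whose genes move together on an array. Alternatives to scaling, to the filter on low values, to the choice of probe set, to the fold threshold and to the random lists were tried. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.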

Results

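The study asked whether heparin, or a peptide modelled on the heparin-binding domain of the chemokine CCL5, had anti-inflammatory effects in rat kidneys reperfused with blood after warm ischaemia and cold storage. Expression was read on 3 arrays, 1 each for saline control, heparin and peptide, and each array held pooled RNA of 3 kidneys. The values are GCRMA log2 expression values. Across all probe sets the arrays correlated at r = 0.996 (heparin and control), 0.998 (peptide and control) and 0.996 (heparin and peptide), which are correlations across probe sets and not across independent samples. The SD of the gene differences was 0.32 for heparin against control, 0.23 for peptide against control and 0.29 for heparin against peptide.

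The first comparison asked what heparin infusion did to the reperfused kidney. Interferon-stimulated genes were higher in the heparin pool than in the control pool, together with genes of antigen processing. Most measured platelet transcripts and markers of the distal and connecting tubule were lower, and podocyte and matrix transcripts were slightly higher. Of 9236 measured genes, 98 were at least 2-fold higher and 69 at least 2-fold lower. At 1.5-fold the balance turned, with 281 higher and 311 lower, and adding 32 to the unlogged values left 74 higher and 40 lower at 2-fold. Ubd, which encodes a ubiquitin-like protein induced by interferon gamma and TNF, was 18.9-fold higher, with log2 values of 7.20 in control and 11.43 in heparin. Next came Spetex2l2 (12.8-fold), Gp2, a glycoprotein of zymogen granules and M cells (12.4-fold), and Poteml2 (10.8-fold). Uba7, the enzyme that activates the ubiquitin-like protein ISG15, was 7.34-fold higher, and a second measured probe set of it gave a log2 difference of 2.11 beside 2.88. Gbp4, a guanylate-binding protein, was 6.08-fold higher. Samhd1, which limits the deoxynucleotides available to viruses, was 5.96-fold higher. Zbp1, a sensor of Z-form nucleic acids, was 5.75-fold higher. Tnfsf10, the death ligand TRAIL, was 5.14-fold higher, and the class I histocompatibility gene RT1-T24-4 was 4.96-fold higher. Genes below the array median in control had only bounds: Rup2 was at least 17.7-fold higher, Batf2, an interferon-induced transcription factor, at least 4.69-fold, and Nlrc5, the transactivator of class I histocompatibility genes, at least 3.56-fold. The Rup2 bound rests on 1 of its 4 probe sets. The others, also below the median in control, had log2 differences of 0.01, 1.45 and 2.58.

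All 25 members of the interferon-stimulated list found on the array were measured in heparin against control. Their median log2 difference was 1.28 (2.43-fold), above all 10000 random lists. Of these, 14 were at least 2-fold higher and 1 was at least 2-fold lower. Usp18, which removes ISG15 from proteins, was higher by 2.21 on the log2 scale, the antiviral GTPase Mx1 by 2.12 and the transcription factor Irf7 by 2.09. The exception was Mx2, whose probe set with the highest mean was at 13.33 in control and 12.16 in heparin, a difference of -1.17. The other probe set of Mx2 went the opposite way, from 8.80 to 11.26. The antigen presentation list had a median of 0.43 over 19 measured genes, above all random lists, with the peptide transporter Tap1 2.98-fold higher and the immunoproteasome subunit Psmb8 also more than 2-fold higher and Psmb10 at 0.83. Of 21 measured chemokines, 3 were at least 2-fold higher and 1 was at least 2-fold lower, with a list median of 0.15. The B cell attractant Cxcl13 was 2.10 higher, the monocyte attractant Ccl7 1.39 higher and the interferon-induced Cxcl10 1.00 higher, whereas Ccl20 differed by -1.36. Among apoptosis genes the inflammatory caspases Casp1 (1.54) and Casp4 (1.08) and Casp12 (1.06) were at least 2-fold higher. That list's median was 0.01, and it became -0.01 when only genes at or above the 60th percentile were used.

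Several tissue compartments also differed between the heparin and control pools. The platelet list had a median of -0.76 over 7 measured genes, below all random lists: the platelet tubulin Tubb1 differed by -1.49, the integrin Itga2b by -0.94, the receptor Clec1b by -0.80 and the chemokine Pf4 by -0.76, while the selectin Selp, also an endothelial gene, was 0.59 higher. With a filter at the 40th percentile this median was -0.15, and without a filter 0.00. Red cell transcripts, which would mark residual blood, had a median of -0.13 over 5 genes, inside the random lists, but single genes went both ways: the haem synthesis enzyme Alas2 differed by -1.14, the membrane protein Gypc by 1.00 and Hbb by -0.24. Distal and connecting tubule markers had a median of -0.39 over 8 genes. Calb1, the calcium-binding protein calbindin of the connecting tubule, was 3.56-fold lower, and tissue kallikrein Klk1, made in the same segment, was 3.21-fold lower. A further kallikrein gene, Klk1c4, was at least 5.97-fold lower. Podocyte markers had a median of 0.34 over 10 genes, with Podxl at 0.74, Ptpro at 0.62 and the transcription factor Wt1 at 0.52. Of these genes 7 were higher, 1 was lower and 2 were identical. Nphs1, the gene of nephrin, named after its value was seen, differed by only 0.04. The heparin array also had a wider gap between the 3' and 5' probe sets of beta-actin than the control array, by 0.61, while the gap of GAPDH differed by -0.04 and that of hexokinase by 0.00. Extracellular matrix genes (0.17), fibroblast, mesangial and smooth muscle markers (0.17) and monocyte and macrophage markers (0.18) lay above the random lists, with Dcn, a collagen-binding proteoglycan, at 0.95 and Fcgr3a, an Fc receptor, at 1.06. The matrix list's largest difference went the other way, Mmp3 at -1.96, and 9 of its 29 measured genes were lower. Immediate early genes (-0.21, with Fosb at -1.36) and fatty acid oxidation genes (-0.20, with the kinase Pdk4 at -0.78 and the peroxisomal enzyme Ehhadh at -0.75) lay below them.

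The largest negative differences with heparin included Stra6, the cell-surface receptor for retinol-binding protein (4.23-fold lower), Golph3 (4.11-fold), Hist4h4 (3.92-fold), the matrix-degrading enzyme Mmp3 (3.88-fold), Slc22a13 (3.75-fold), the PI3-kinase regulatory subunit Pik3r1 (3.55-fold), Tpcn2 (3.37-fold) and Atosb (3.10-fold). The Stra6 value rests on 1 of its 3 probe sets above the median, since the others differed by 0.00 and -0.09. Smaller list medians outside the random lists were those of chemokine receptors (0.13, with Ccrl2 at 1.38), adhesion molecules (0.12, with Vcam1 at 0.60 and the endothelial selectin Selp at 0.59), complement (0.09, with C1r at 0.87), pro-inflammatory cytokines and NF-kB targets (0.08, with Il18 at 0.89), collecting duct markers (0.03) and coagulation and fibrinolysis (-0.12). In the last list tissue factor, F3, differed by -1.09 and the protease inhibitor Serpine2 by 1.06. In all, 18 of 36 lists lay outside the random lists, 13 above and 5 below, where 1.80 would be expected if lists behaved like random sets. Of these 18, 11 kept their side in all 9 other settings and 7 did not: the platelet, chemokine receptor, pro-inflammatory, complement, coagulation, apoptosis and collecting duct lists. Some that kept their side had much smaller medians without the filter on low values: chemokines 0.00, fibroblast, mesangial and smooth muscle markers 0.02, distal and connecting tubule markers -0.14 and podocyte markers 0.16.

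**Figure D1:**
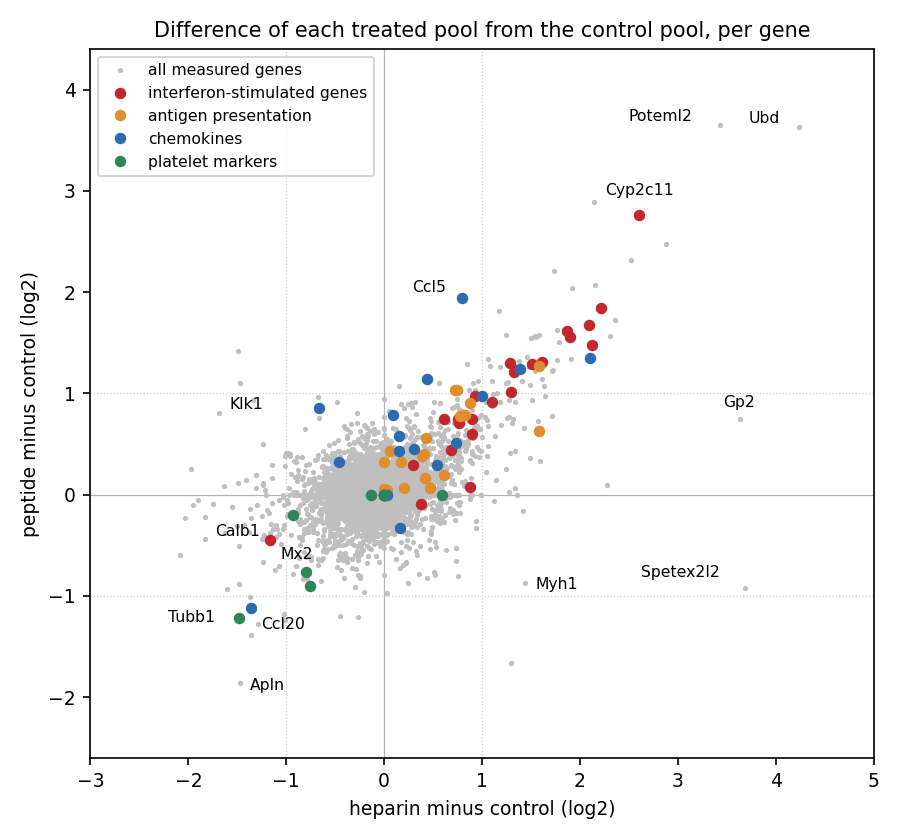
Log2 difference of each measured gene between the heparin and control arrays (horizontal axis) and between the peptide and control arrays (vertical axis), 1 pooled array per group, with the control array entering both axes. Coloured points are members of 4 gene lists, dotted lines mark 2-fold, and the interferon-stimulated genes lie mostly in the upper right, where 53 genes were at least 2-fold higher in both comparisons.

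The second comparison asked the same of the peptide. The peptide pool differed less from control than the heparin pool did, and most of its larger differences were positive: of 9268 measured genes, 67 were at least 2-fold higher and 11 at least 2-fold lower. Interferon-stimulated genes were again higher as a list, and several chemokines, among them Ccl5 itself, were higher than in control. Poteml2 was 12.6-fold higher and Ubd 12.4-fold higher. Cyp2c11, a male-specific cytochrome P450 of rat liver, was 7.43-fold higher, and it was 4.43-fold higher with heparin. Its control value, 4.585, lay close to the array median. Samhd1 (6.83-fold), Gbp4 (6.79-fold), Uba7 (5.57-fold), Zbp1 (4.97-fold), Parp10, an ADP-ribosyltransferase (4.61-fold), Gbp7 (4.19-fold) and the sterol hydroxylase Cyp27a1 (4.10-fold) followed. With heparin, Parp10 was 3.32-fold, Gbp7 4.46-fold and Cyp27a1 3.77-fold higher than in control. Ifnb1, the gene of interferon beta, was under the array median in control (3.31) and at 6.38 in peptide, at least 4.71-fold higher. Its heparin value was 5.16. Batf2 was again at least 4.69-fold higher.

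The interferon-stimulated list had a median of 0.99 (1.99-fold) over 24 measured genes in peptide against control, above all random lists, with 12 genes at least 2-fold higher and 0 at least 2-fold lower. Gbp4 was at 2.76, Usp18 at 1.84, Irf7 at 1.68 and Gbp2 at 1.61, while Mx2 (-0.45, with its other probe set at 1.94) and Ifi27 (-0.09) were the measured members that were lower. Ifit1 was the member that was not measured here, and it and its relatives are described because of their values: it read 4.93 in control, 6.91 in heparin and 3.31, below the array median, in peptide, while Ifit2 was 1.29 higher and Ifit3 1.02 higher in peptide than in control. Antigen presentation genes had a median of 0.40 over 19 genes, all 19 of them higher, led by Tap1 (1.27), Tap2 (1.04) and the immunoproteasome subunit Psmb9 (1.04). Chemokines had a median of 0.44 over 21 genes, above all random lists, with 4 at least 2-fold higher and 1 at least 2-fold lower. Ccl5, the parent of the peptide, was 3.84-fold higher (8.60 in control, 10.54 in peptide), Cxcl13 2.55-fold, Ccl7 2.36-fold and the monocyte attractant Ccl2 2.21-fold. Ccl20 was 2.18-fold lower. This median was 0.00 without the filter on low values. Casp1 (1.57) and Casp4 (1.27) were at least 2-fold higher, as was Fcgr3a (1.34) among macrophage markers, whose median was 0.04 and which also include Gpnmb (-1.21). Toll-like receptor signalling genes had a median of 0.13, with the kinase Irak2 at 0.62.

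Platelet markers had a median of -0.20 over 7 genes in peptide against control, 4 of them lower, with Tubb1 at -1.22, Pf4 at -0.90 and Clec1b at -0.76. The median was 0.00 with a filter at the 40th percentile and with no filter. Red cell transcripts had a median of -0.06, inside the random lists, with Gypc at 0.57 and Alas2 at -0.34. Distal and connecting tubule markers had a median of -0.17, which was also 0.00 under those filters, and Calb1 was at -0.22 while Klk1 was 0.81 higher. Tubular injury markers had a median of -0.05 over 21 genes: Lcn2, a protein released by injured tubules and by neutrophils, was 2.26-fold lower, Havcr1 (kidney injury molecule) 1.89-fold lower and Clu was at -0.68, whereas Sprr1a was at 0.83. The other genes with the largest negative differences were Apln, the ligand of the apelin receptor (3.64-fold lower), the immunoglobulin gene Ighl2 (3.16-fold), the short branched-chain acyl-CoA dehydrogenase Acadsb (2.62-fold), Csrp3 (2.43-fold), the transporter Slc7a12 (2.37-fold), Gpnmb (2.32-fold) and Sh2b2 (2.30-fold).

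Of 36 lists, 14 lay outside the random lists in peptide against control, 9 above and 5 below, but several by small amounts. Besides those already given these were proximal tubule markers (0.05), apoptosis genes (0.04), oxidative stress genes (0.04), oxidative phosphorylation (0.03), podocyte markers (-0.06) and extracellular matrix (0.00, just below random lists that were themselves at 0.00). The interferon, antigen presentation, toll-like receptor and proximal tubule lists kept their side in all 9 other settings, and the other 10 did not.

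**Figure D2:**
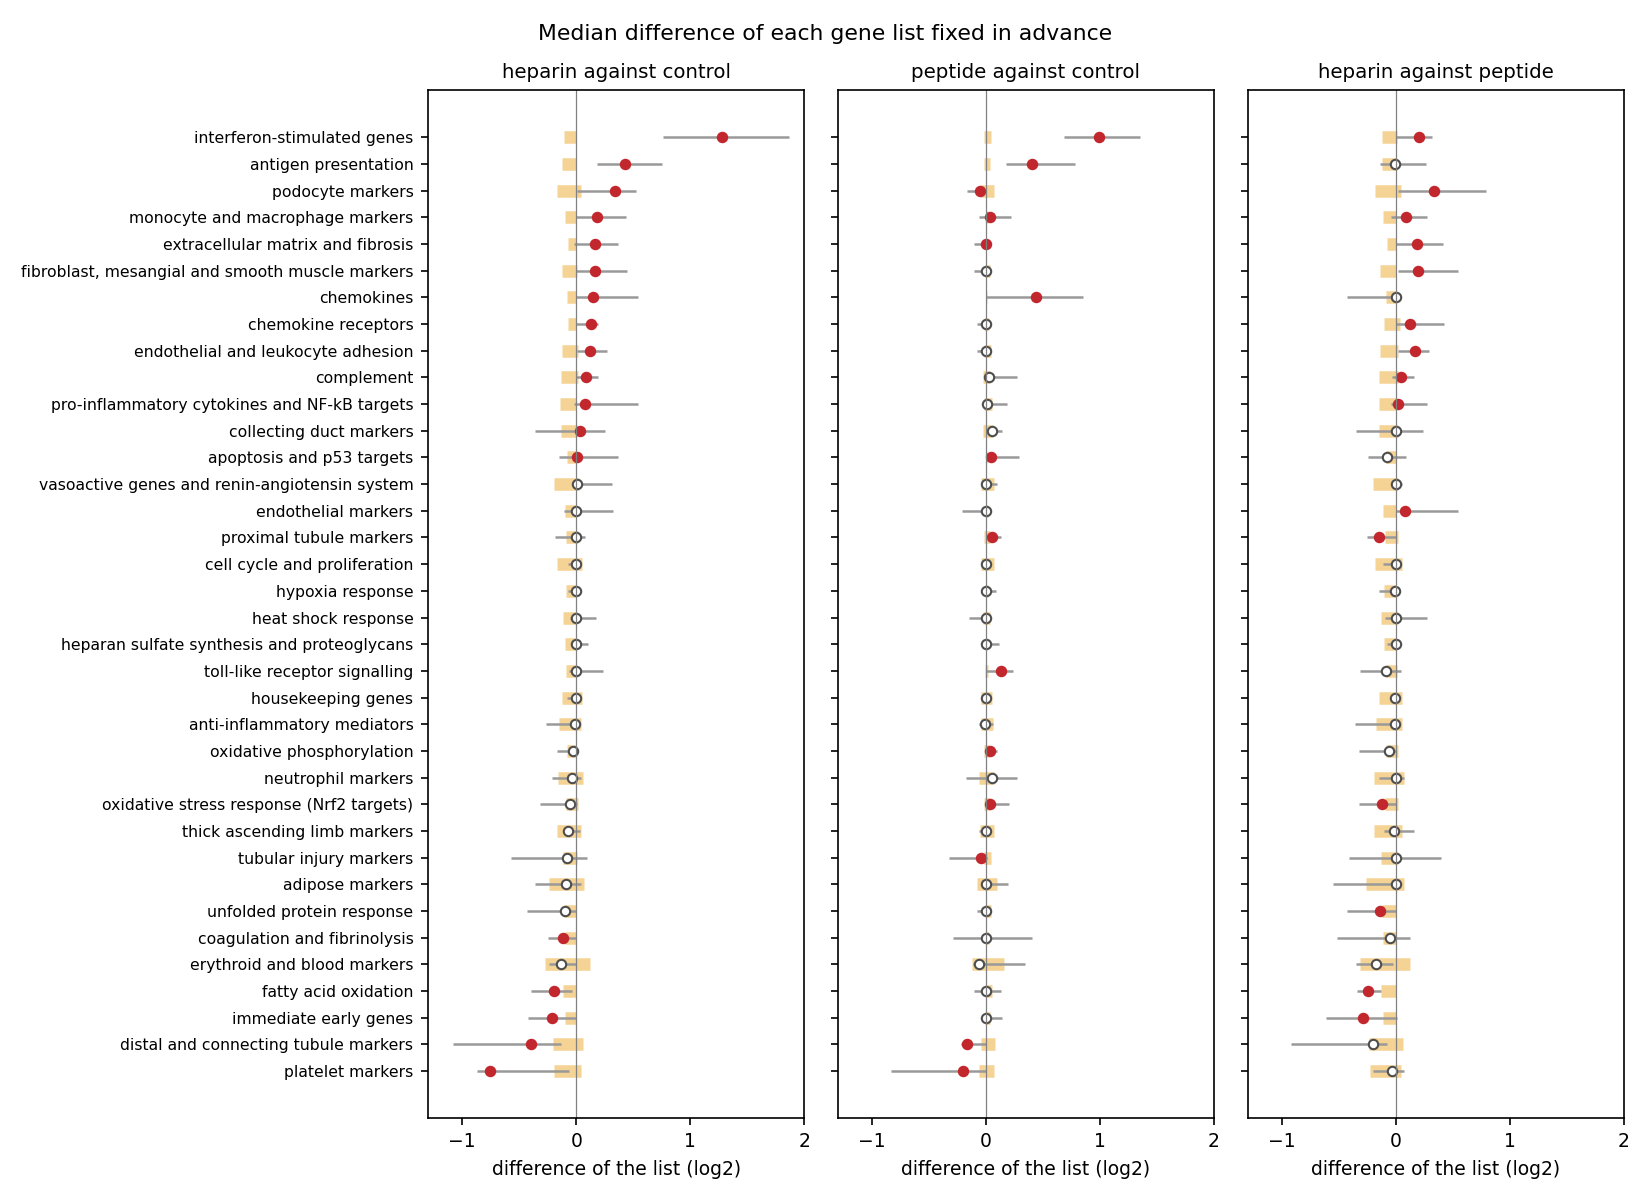
Median log2 difference of each gene list with at least 5 measured members in the heparin comparison, for the 3 comparisons of 1 array each, with red points outside and open points inside the central 95% of 10000 expression-matched random lists (yellow bars), and grey lines spanning the quartiles of the list's members. The interferon-stimulated list is farthest to the right in both comparisons with control, at 1.28 and 0.99, and the platelet list farthest to the left, at -0.76 and -0.20.

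Heparin and peptide were then compared directly. Transcripts were more often lower in the heparin pool: of 9240 measured genes, 26 were at least 2-fold higher and 78 at least 2-fold lower (36 higher and 57 lower after quantile normalization of the arrays, 49 and 88 with no filter, 13 and 59 with the mean of a gene's probe sets, 16 and 57 with a filter at the 60th percentile, and 15 and 40 after adding 32 to the unlogged values). The kallikrein genes Klk1b3 and Klk1 were 5.93-fold and 5.62-fold lower in heparin, and lower too were the interleukin 23 subunit Il23a (a log2 difference of -2.91), the methyltransferase Inmt (4.85-fold) and Hist4h4 (4.65-fold). Spetex2l2 was 24.3-fold higher in heparin, Ighl2 7.78-fold, Gp2 7.42-fold, Myh1 4.95-fold and the carbonic anhydrase Car3 4.52-fold. The name Myh1, a fast skeletal muscle myosin, carries a limit. Its 5 probe sets read from 10.73 to 14.48, and all 5 were higher in heparin than in peptide. The highest value of the other 21 members of the skeletal muscle list found on the array was 4.66.

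The interferon-stimulated list differed by a median of 0.20 between heparin and peptide over 24 measured genes, of which 0 were at least 2-fold apart. This median lay above all random lists, with 18 genes higher in heparin, 5 lower and 1 identical. The largest differences were those of Bst2 (0.80), Mx2 (-0.72, with its other probe set at 0.52) and Mx1 (0.64). Ifit1, not measured in peptide, is outside this count and read 6.91 in heparin and 3.31 in peptide. Antigen presentation genes had a median of 0.00 and chemokines 0.00. Within the chemokines, however, Ccl4 differed by -1.52 and Ccl5 by -1.15, both lower in heparin. The chemokine receptor Ccr1, a receptor for CCL5, was 0.89 higher in heparin. Podocyte markers had a median of 0.34, with Wt1 at 1.31 and Ptpro at 0.82. Fibroblast, mesangial and smooth muscle markers (0.20, with Col3a1 at 0.65), extracellular matrix (0.19, with Tnc at 0.77 but Mmp3 at -1.85), adhesion molecules (0.17, with Jam2 at 0.77), chemokine receptors (0.12), macrophage markers (0.09), endothelial markers (0.08, with the VEGF receptor Kdr at 0.88), complement (0.04) and pro-inflammatory genes (0.02) also lay above the random lists. Immediate early genes (-0.29, with Fosb at -1.12 but Nr4a3 at 1.12), fatty acid oxidation (-0.24), proximal tubule markers (-0.15, with the glucose transporter Slc5a2 at -0.47), the unfolded protein response (-0.14, with the chaperone Dnajb9 at -0.94) and oxidative stress genes (-0.12, with Gsr at -1.39 and Srxn1 at -1.07) lay below them. The coagulation and fibrinolysis list had a median of -0.05, inside the random lists, with 7 of 21 measured genes higher in heparin and 11 lower. Fga (-1.41, with its other probe set at -0.28), the urokinase Plau (-1.09) and its receptor Plaur (-0.91) were lower. The protein C receptor Procr (1.26) was higher. Of the 15 lists outside (1.85 expected among 37), the chemokine receptor, pro-inflammatory, complement, proximal tubule and endothelial lists did not keep their side in all 9 other settings, and the remaining 10 did. The gap between the 3' and 5' probe sets of beta-actin was 2.95 on the heparin array and 2.34 on the peptide array. For GAPDH the gaps were 0.32 and 0.37, and for hexokinase 2.18 and 2.28. A difference in RNA quality between these pools therefore remains open.

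Across the 9231 genes measured on all 3 arrays, the differences of heparin and of peptide from control correlated at r = 0.48 (Spearman's rho 0.21), a correlation across genes that shares 1 control array. Simulated arrays without any effect gave r = 0.50 (0.47 to 0.53) from the shared control alone. Equally noisy arrays with 1 shared control give r near 0.50 whatever the size of the noise, so this comparison decides nothing. The real SDs were unequal, at 0.32 (heparin against control), 0.23 (peptide against control) and 0.29 (heparin against peptide). The covariance was 0.0357 against a simulated 0.0446, a difference of -0.0089, so the simulated noise was not matched to these arrays. The simulated counts that follow carry the same limit. By count, 53 genes were at least 2-fold higher with both treatments, where simulation gave a mean of 12.6 and at most 27. Independent lists would share 0.694. Downwards, 8 genes were shared, where simulation gave 12.7 and at most 26, and independent lists 0.0822. Part or all of the excess may come from the shared control, which is a single array and cannot be split. Of the 53 genes higher in both, 12 belonged to the interferon-stimulated list, 1 to antigen presentation and 2 to chemokines. The 8 lower in both were Acadsb, Apln, Ccl20, Csrp3, Lcn2, Npy, Slc7a12 and Tubb1, of which Npy was named after its value was seen. The heparin array stood at least 2-fold below both others for 40 genes and above both for 13, and the peptide array below both for 1 and above both for 3.

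**Figure D3:**
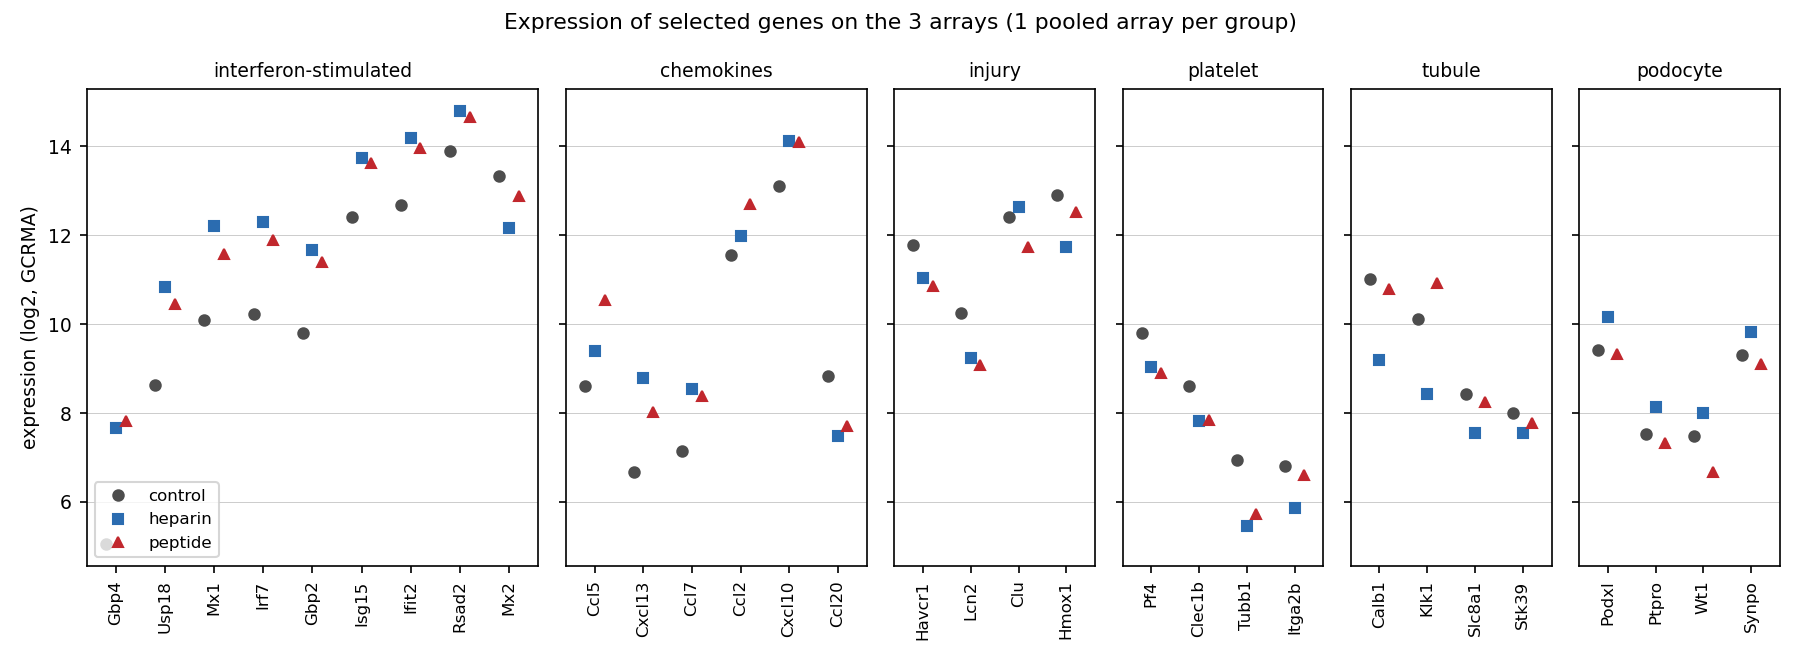
Log2 expression on the control (circles), heparin (squares) and peptide (triangles) arrays for genes in 6 panels, chosen for display after their values were seen, each point being 1 array of pooled RNA. Hmox1, shown in the injury panel, belongs to the anti-inflammatory and oxidative stress lists and not to the tubular injury list. Of the interferon-stimulated genes shown, all but Mx2 lie higher on both treated arrays than on the control array, Ccl5 is highest with peptide (10.54), and Calb1 and Klk1 are lowest with heparin (9.19 and 8.43).

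For the genes the study's subject singles out, Ccl5 was 1.73-fold higher with heparin and 3.84-fold higher with peptide than in control. Its receptor gene Ccr1 was at 0.16 and -0.73, and Ccr3 sat at the lowest value of the scale on every array. Ccl2 was at 0.44 with heparin and 1.15 with peptide. The adhesion molecule Icam1 differed little, at 0.07 and -0.11, and Vcam1 was at 0.60 and 0.28. Havcr1 was lower by 1.66-fold and 1.89-fold, and Lcn2 by 2.04-fold and 2.26-fold, but other tubular injury markers were higher, such as Il18 with heparin (0.89) and Sprr1a with peptide (0.83). Hmox1, the haem-degrading enzyme induced by oxidative stress, was 2.25-fold lower with heparin and 1.30-fold lower with peptide. The heparan sulfate and proteoglycan list, of interest because both agents relate to heparin binding, had a median of 0.00 in all 3 comparisons, with Gpc1 at 0.56 and Sdc4 at 0.26 the members most above 0 with heparin and with peptide. Neutrophil markers had medians of -0.04 and 0.05 against control, inside the random lists, with Lcn2 the only member at least 2-fold apart in either. T cell and NK cell, B cell and plasma cell, skeletal muscle and adrenal lists had fewer than 5 measured members against control, and 22 of 27 T cell and NK cell genes were below the median on all 3 arrays. The lists on anti-inflammatory mediators, the heat shock response, hypoxia, cell cycle, housekeeping genes, vasoactive genes, the thick ascending limb and adipose markers lay inside the random lists in all 3 comparisons, with medians from -0.09 to 0.01. Other lists lay inside in some comparisons only. For heparin against control these were the unfolded protein response (-0.10), tubular injury markers (-0.08), oxidative stress genes (-0.05), oxidative phosphorylation (-0.03), and toll-like receptor signalling, proximal tubule and endothelial markers (0.00 each). For peptide against control they were collecting duct markers (0.06), complement (0.02), pro-inflammatory genes (0.01), and at 0.00 chemokine receptors, adhesion molecules, coagulation, immediate early genes, the unfolded protein response, fatty acid oxidation, endothelial markers and fibroblast, mesangial and smooth muscle markers. For heparin against peptide they were distal and connecting tubule markers (-0.20), toll-like receptor signalling (-0.08), apoptosis genes (-0.08), oxidative phosphorylation (-0.06), platelet markers (-0.04), and tubular injury and collecting duct markers (0.00 each). Between the treatments red cell transcripts (-0.17), neutrophil markers (0.00) and T cell and NK cell markers (0.00) lay inside as well.

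Probe sets gave a check within the arrays. For genes with at least 2 measured probe sets, the differences of the first and second probe sets correlated across genes at r = 0.40 (heparin against control), 0.49 (peptide against control) and 0.35 (heparin against peptide). When the first probe set was at least 2-fold different, the second had the same sign in 21 of 25, 9 of 9 and 21 of 24 genes, and was itself at least 2-fold different in 9, 6 and 4. A 2-fold difference of a single gene with 1 probe set therefore carries both the unknown spread between pools and a spread between probe sets, whose SD was 0.253, 0.160 and 0.236.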

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

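The signals here lie in probe sets that enter no comparison of genes, and the tests weighed below were chosen after the results were seen. On the heparin array the control probe set for 5S ribosomal RNA was higher than on the control array by 2.02 on the log2 scale, and the probe set ratb1 for a repeat element by 0.877. The spiked hybridisation controls, added in equal amounts to each array in the usual protocol, had a median heparin minus control difference of 0.454 and a median peptide minus control difference of -0.39. The poly-A controls differed by medians of 0.326 and -0.75. Between heparin and peptide the medians were 0.872 and 1.14, with every one of these control probe sets higher on the heparin array (lowest differences 0.448 and 0.615). These are larger than every list median between the treatments, of which the largest was 0.337, and the cause was not tested. Of 2918 measured probe sets without a gene symbol, 71 were at least 2-fold higher and 26 lower with heparin than in control, and 27 were higher and 19 lower with peptide.

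In both treated pools interferon-stimulated genes were higher than in the control pool. On these arrays, a rise of monocytes and macrophages in proportion to the interferon genes is argued against. Their markers had medians of 0.037 (peptide) and 0.179 (heparin), and adding 2 bootstrap SDs gave 0.125 and 0.397. Both lay below 0.5 times the interferon medians, 0.497 and 0.641. That mark was set after the results were seen, and a bootstrap over genes holds no spread between pools. The marker list still lay above the random lists in both comparisons, so a smaller rise of these cells remains open. Cross-hybridising probe sets could not be judged. Probe sets with names ending in _s_at, _x_at or _a_at were left out, although such an ending does not by itself show cross-hybridisation. Then 23 of 25 genes (heparin) and 22 of 24 (peptide) remained, with medians of 1.10 and 0.943. The lower quartiles of the full list, 0.764 and 0.680, already lay above 0.5 times its medians. Leaving out so few genes could therefore not have brought the median below that mark. A control pool that was low by chance or through its 3 animals remains open and cannot be told apart from an effect of both treatments. The treated pools differ from each other by a median of 0.204, above all random lists. That is less than either median against control, as both explanations predict, and the control is 1 array. The induction of interferon-stimulated genes by both treatments is thus only a hypothesis.

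The heparin pool had lower connecting tubule genes and higher podocyte and matrix genes. More degraded RNA in that pool could not be excluded. The gap between 3' and 5' probe sets was wider by 0.614 for beta-actin but differed by -0.04 for GAPDH and by 0.00 for hexokinase. The 5' set of GAPDH and the 3' set of hexokinase had identical values on all 3 arrays, so those gaps say little. Heparin minus control, the beta-actin sets differed by -0.14 (3'), -0.52 (middle) and -0.75 (5'). A larger share of glomeruli in the tissue taken is also open, because the SD of the podocyte differences, 0.316 over 10 genes, lay above the SD between probe sets of a gene, 0.253, but not above double that. An effect of heparin itself on these cells was not tested and remains possible in the same way.

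The median of 7 measured platelet transcripts was lower in both treated pools, with 5 genes lower with heparin and 4 with peptide, and it did not hold under every filter on low values. Less residual blood may account for it, but red cell transcripts, with medians of -0.133 (heparin) and -0.064 (peptide), do not decide: subtracting 2 bootstrap SDs gave -0.887 and -0.548, and the 5 measured red cell genes went both ways. An effect of heparin or of the peptide on platelet deposition is a further open explanation, and no test here separates them.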

How the results depend on the processing

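The alternatives were chosen before the data were examined, except leaving out the interferon-stimulated and antigen presentation lists, which was chosen after. Leaving out a replicate was not possible with 1 array per group, and no paired analysis was possible because no group has a second sample. Subtracting the median difference moved nothing, since that median is 0, and says nothing about stability. At 1.5-fold, the counts higher and lower were 281 and 311 (heparin against control), 196 and 85 (peptide against control) and 150 and 422 (heparin against peptide). At 3-fold they were 34 and 12, 17 and 2, and 6 and 14. Adding 32 to the unlogged values left 40 genes lower with heparin, 6 lower with peptide, and 15 higher and 40 lower in heparin against peptide. A filter at the 60th percentile gave 7 genes lower with peptide and 16 higher in heparin against peptide. For the latter, no filter gave 49 and the mean of a gene's probe sets 13. Lists outside the random lists numbered 11 (heparin against control) and 7 (peptide against control) with no filter, and 9 (peptide against control) with the 40th percentile. The median of the apoptosis list with heparin was -0.0086 at the 60th percentile. The correlation of both treatments' differences was 0.422 with no filter, 0.507 with the mean of probe sets and 0.441 without the interferon and antigen presentation lists. The filter and the offset act by admitting or damping values near the lower end of the scale. For the other settings the cause was not tested. Other counts stayed within 1.5 times. The median of the interferon list ranged from 1.10 to 1.30 with heparin and from 0.942 to 1.00 with peptide. Of 323 alternative values of named genes, 275 moved by less than the SD between probe sets and 48 by more. A change of sign was looked for only in differences of at least 2-fold, of which 0 reversed. The filters on low values were not among the settings tried for named genes. Alternative list medians were followed only for the 47 results that lay outside the random lists in the main setting. Of 374 such medians, 353 moved by less than a bootstrap SD of the list, 20 by more and 1 reversed. The data are limited by the single array per group and by signal near background, with 30.9% of probe sets on the control array at the lower end of the scale.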

Other observations

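Genes in this part were chosen after their values were seen. Of the 53 genes at least 2-fold higher in both treated pools, 34 belonged to none of the fixed lists, and no test of gene groups was run on them. The helicase Ddx60 was 2.83-fold higher with heparin and 2.93-fold higher with peptide. On the log2 scale the ubiquitin ligase Rnf213 was higher by 1.46 and 1.36, the chaperone Rtp4 by 1.54 and 1.22, the nuclear body protein Sp110 by 1.61 and 1.14, the RNA helicase Znfx1 by 1.71 and 1.22, and the exonuclease Isg20 by 1.19 and 1.26. The immunity-related GTPases Irgm (1.49 and 1.09) and Irgm2 (1.41 and 1.12) and Slfn5 (1.25 and 1.10) belonged to the same set. The nucleoside transporter Slc28a2 was higher by 1.63 and 1.07, and the activation marker Cd69 by 1.18 and 1.82.

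Some genes set the heparin array apart from both others. Of kallikrein genes, 3 are given here, without a count of the rest of the family: Klk1 read 10.12 in control, 8.43 with heparin and 10.92 with peptide, Klk1b3 read 11.18, 9.71 and 12.28, and Klk1c4 read 6.74, 2.78 and 7.39. The transcripts Jchain (5.30, 6.72 and 5.14) and Ighl2 (5.86, 7.16 and 4.20) were highest there. Lower in heparin than in both others were also the nuclear receptor Rora (-1.15 against control and -1.31 against peptide), the chaperone Hyou1 (-1.43 and -1.12), glutathione reductase Gsr (-1.01 and -1.39), the prostaglandin synthase Ptgds (-1.41 and -1.55) and the activity-regulated gene Arc (-1.55 and -1.43).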
